A study of Caenorhabditis elegans with 2 samples.

How the data were processed

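Chromatin was immunoprecipitated with an antibody against GFP from whole L4 hermaphrodites of strain OP398, which carries DVE-1 with a C-terminal GFP-FLAG tag, and was fragmented by sonication, per the labels. The deposited files were narrowPeak lists without header on the ce10 and ce11 assemblies. For each assembly there was a relaxed list of peaks and background for each of the 2 replicates and for the pooled replicates, with 30000 regions each, and an optimal list that passed a threshold on the irreproducible discovery rate (IDR). Per the text deposited beside the lists, each relaxed list derives from the alignment of the sample and 1 control alignment that is shared by both replicates and the pooled list. The optimal list derives from both replicate lists and the pooled list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here, and the control library was not analysed here.

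Each region has a deposited signal value, as the authors' peak caller gave it against the control, and a deposited -log10 q value. The signal is on a scale of its own in each list, so it was used to rank and describe peaks within a list, and the values of both replicates were compared as ranks or after division by each replicate's median over the optimal peaks. The -log10 q value reached 1 highest value per list (4.27 in the pooled ce11 list), shared by 9360 pooled regions, and was not used for ranking. The optimal ce11 list was found to be the 7262 strongest regions of the pooled list. Because signal at a peak is relative to a shared control, an error of the control at a locus would appear in both replicates. The lists give no read counts, so the depth of each library is unknown.

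Positions were compared with the Ensembl release 115 gene annotation and the matching genome sequence, whose chromosome lengths fit the ce11 lists. The ce10 lists were used for counts of peaks, overlap and correlation only, and no coordinates were converted. A promoter window ran from 1000 bp upstream to 200 bp downstream of each of 29314 annotated 5' ends of 19973 protein-coding genes on the 6 nuclear chromosomes. A gene was counted as marked when an optimal summit fell in any of its windows. The summit can thus lie inside the gene, before an internal 5' end, as at zip-3, hsp-90, cox-6B, zip-2 and gld-2. Summits outside these windows were assigned in order to coding exons, untranslated exons, introns, the 1000 bp downstream of a gene or elsewhere.

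Replicate overlap, promoter share and small RNA gene share were tested one-sided against 10000 circular shifts along each chromosome (100 where intervals were compared with bedtools 2.31.1). The X share was tested by an exact binomial test, the signal of promoter peaks by 100000 permutations with a bootstrap interval from 1000 draws, and 24 gene lists by Fisher's exact test (two-sided). The 6-mers were tested by an exact McNemar test. The Benjamini-Hochberg adjustment was applied over the 24 lists and over the 2080 6-mers, with a threshold of 0.05. Confidence intervals are 95% exact binomial. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

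The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Of the members of the lists, hsp-16.11 and hsp-16.49 did not match the annotation, and lists chosen by symbol pattern include every annotated match. The rule named the genes of the 15 strongest promoter peaks, every member of both mitochondrial lists, unc-119, up to 4 members with the strongest peak for each other list that passed and up to 2 for each that did not. It also named the 10 6-mers with the lowest adjusted p among those more frequent at summits and the 5 among those less frequent. Genes outside this rule (Y22D7AL.10, C37H5.5, Y37E3.8, F15D3.6, F29B9.11, pqn-59, sls-2.1, sls-2.4) and the sequence GAGACGCAG were named after their values were seen. Alternatives covered the peak set (the strongest 3631 peaks, each replicate alone, the strongest pooled regions), windows and distances, the background, the assignment of peaks to genes, the assembly and the flanks of the 6-mer test. A further alternative, without the 418 peaks near small RNA genes, was added after the data were seen.

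The tests were checked on simulated data. Over 100 simulations with the 19973 genes, 6 of 24 lists had raised or lowered chances of a peak. Of those lists 95.0% were called (75.0% for the hardest), as were 0.833% of the 18 others. Each gene was drawn on its own there, whereas in the data a peak between divergent genes can mark both. This dependence was not simulated. In 3000 simulated sequences with 1 planted 6-mer, that 6-mer was called and none of the other 2079 were. These sequences had the same base composition at summits and flanks. The check therefore does not cover calls that come from a difference in GC content, which the data have. The shift test called 0 of 20 sets of 7200 random positions.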

Results

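Binding of DVE-1, a homeodomain protein of the SATB family known for its part in the mitochondrial unfolded protein response, was measured by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans. The animals were L4 hermaphrodites, the last larval stage, of a strain with a transgene for DVE-1 fused at its C-terminus to GFP and FLAG, and the fusion protein was recovered with an antibody against GFP. There was 1 group with 2 biological replicates, which the labels trace to separate biosamples. With no second condition among the samples analysed, the comparisons were between the replicates, between peaks and shifted positions, between groups of genes and between summits and their flanks. The optimal list held 7262 peaks on the ce11 assembly, with a median width of 364 bp, and its regions covered 2.3% of the genome. These lists give no read counts, so the depth of each library is unknown, and intervals on shares cover counting error over peaks or genes.

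The first question was how far both replicates marked the same places. Of the 7262 strongest regions of replicate 1, 5190 (71.5%) had a summit within 100 bp of a summit among the 7262 strongest of replicate 2, against a mean of 1.48% and a highest value of 3.08% when replicate 1 was shifted along each chromosome (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). The promoters of rpl-3, which encodes a protein of the large ribosomal subunit, and of the divergent pair rpl-15 and K11H12.8 held the same rank in both, the first and the fourth place. Peak strength followed the same order less tightly. An optimal peak was counted as found in both replicates when the relaxed list of each had a summit within 100 bp. This held for 6828 peaks (94.0%), while 5200 optimal peaks (71.6%) were among the 7262 strongest regions of both. Over the 6828 peaks, Spearman's rho was 0.71 and Pearson's r of the log2 signal was 0.69. Both were taken across peaks, which are not independent replicates and were selected on the pooled signal. The log2 ratio of replicate 1 to replicate 2 had an SD of 0.66 across peaks, so peaks of similar strength could not be ordered.

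**Figure D1:**
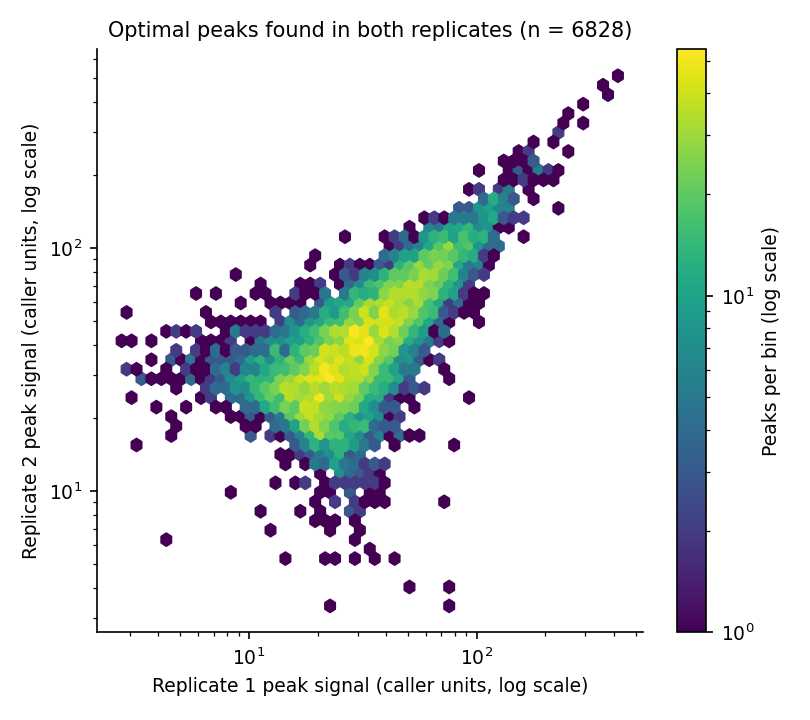
Signal of each optimal peak found in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both in the peak caller's units on log scales, with colour for the number of peaks per bin. The 6828 peaks follow one band (rho 0.71) that is narrow for the strongest peaks and wide for the weakest.

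Of the 15 strongest promoter peaks, 6 were at genes for cytosolic ribosomal proteins, namely rpl-3, rpl-20, rpl-15, rpl-35, rps-19 and rpl-12. The peak upstream of rpl-3 (chromosome III, 3867407 to 3867760) was the strongest of all, with a signal of 918 in the pooled list. Relative to the median optimal peak of each replicate it reached 13.8 ± 0.44 (SD, n = 2), and its summit lay 276 bp before the 5' end of the gene. The second place was shared by rpl-20 and Y17G9B.5 (chromosome IV, 4749901 to 4750234) at a relative signal of 12.1 ± 0.89 (SD, n = 2). Next came cdc-48.1, which encodes an AAA ATPase of protein quality control (chromosome II, 10563411 to 10563739), at 12 ± 0.19 (SD, n = 2). Between 5.99 and 10.4 times the median followed the peaks at rpl-15 with K11H12.8, tasp-1 with K01G5.10, rpl-35, the histone gene his-37, iff-2 with F54C9.14, cox-5A, H41C03.3, hsr-9 with rps-19, egg-5, puf-9, rpl-12 with lin-54, and serp-1.1. The gene cox-5A encodes a subunit of cytochrome c oxidase, iff-2 the translation factor eIF5A, and lin-54 a subunit of the DREAM complex. The peaks assigned to H41C03.3 and egg-5 also lay within 300 bp of the genes sls-2.1 and sls-2.4, which encode SL2 spliced leader RNA. A peak between divergent genes was counted once and cannot be assigned to either of them.

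Summits were concentrated upstream of protein-coding genes. In 3992 of 7262 peaks (55%, 95% exact interval 53.8 to 56.1) the summit fell between 1000 bp upstream and 200 bp downstream of an annotated 5' end, against a mean of 25.8% and at most 30.8% for shifted peaks (one-sided p = 0.0001, the smallest that 10000 shifts can give). The median promoter summit lay 184 bp upstream of the 5' end, but the window itself lies mostly upstream, which favours such a median. Coding exons held few summits, with 164 peaks (2.26%) against 19.0% of the genome after promoter windows are taken out, while untranslated exons held 156 (2.15%) against 2.73% of the genome. Introns held 1133 peaks (15.6%, against 27.1% of the genome), regions within 1000 bp downstream of a gene held 515 (7.09%) and 1302 (17.9%) lay elsewhere. Among the 7262 weakest regions of the pooled list, which lie outside the optimal peaks, 24.7% of summits were in promoter windows, 37.9% in introns and 14.2% in coding exons. Promoter peaks were slightly stronger than others, with medians of 66.9 and 61.8 and a log2 difference of 0.11 (bootstrap interval 0.06 to 0.16, two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Within the 3631 strongest peaks this difference was 0.02 (permutation p = 0.504), and peaks are not independent replicates.

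**Figure D2:**
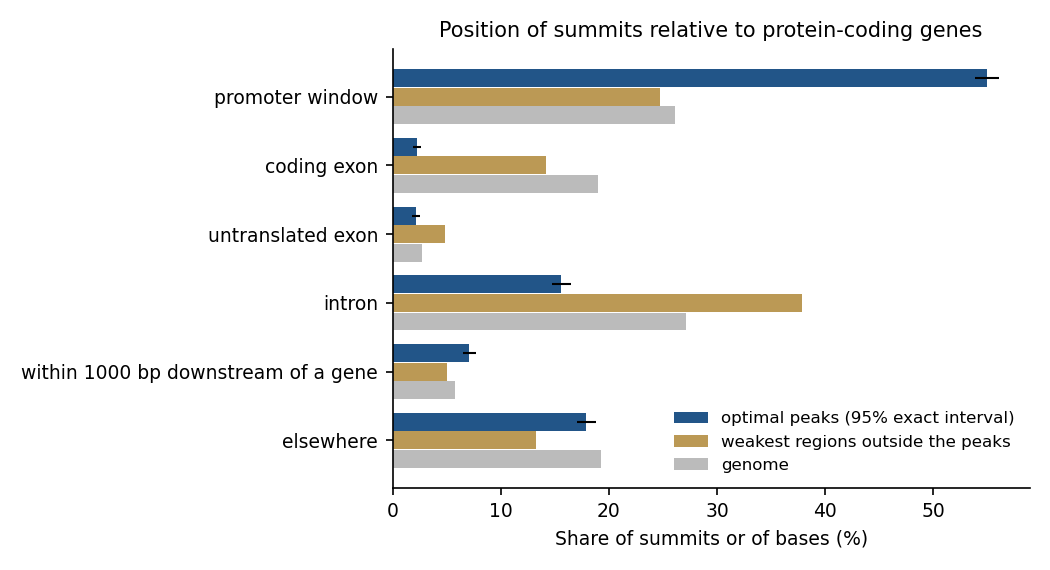
Share of summits in each position class relative to protein-coding genes, for the optimal peaks (bars with 95% exact intervals) and the weakest regions of the pooled list, beside the share of bases in the genome, on an x axis in percent. Promoter windows hold 55% of peak summits, 24.7% of weak summits and 26.1% of the genome.

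DVE-1 is known as a regulator of mitochondrial stress genes, and the next comparison asked which of them had a peak. The list of mitochondrial chaperones and proteases held 17 genes, and it also took in import genes, the prohibitin genes, sod-2, prdx-3, trx-2 and haf-1. Of these 17 genes, 9 had an optimal peak in the promoter window (52.9%), against 4327 of all 19973 protein-coding genes (21.7%). The log2 odds ratio was 2.02 ± 0.68 SE (Fisher's exact test, adjusted p = 0.00686). The strongest was hsp-60, which encodes the mitochondrial chaperonin, with a peak 610 bp upstream (chromosome III, 1619006 to 1619263) at 4.17 ± 0.82 times the median optimal peak (SD, n = 2) and rank 79. Its summit was also 203 bp upstream of the divergent gene Y22D7AL.10, the worm homolog of the co-chaperonin HSP10. The peak of hsp-6, the mitochondrial HSP70 gene, lay 410 bp upstream (chromosome V, 4827083 to 4827276) at 2.45 ± 0.28 (SD, n = 2) and rank 552, and 190 bp from the divergent gene C37H5.5. The import genes tomm-20 (2.61 ± 0.09), timm-17B.1 (1.53 ± 0.40) and timm-23 (1.5 ± 0.08), and the prohibitin genes phb-1 (1.27 ± 0.20) and phb-2 (0.93 ± 0.29), also had peaks (SD, n = 2). The phb-1 summit was nearer to its divergent neighbour Y37E3.8 (277 bp) than to phb-1 (468 bp), and the timm-23 summit was 884 bp upstream of F15D3.6. The protease genes ymel-1 and clpp-1 had weak peaks, at ranks 4379 and 6086. At ymel-1 both replicates had a region among their 7262 strongest in the window, that of replicate 1 more than 100 bp from the optimal summit. No optimal peak was present in the windows of dnj-10, haf-1, lonp-1, prdx-3, sod-2, spg-7, tomm-22 and trx-2, although 4 of these 8 held a region of the relaxed pooled list, the highest being spg-7 at rank 7665, and haf-1 held a region among the 7262 strongest of replicate 1 alone. The call was lost when each peak was given only to the nearest 5' end within 2000 bp, which also replaced the promoter window. It was lost too among genes with any region of the pooled list in the window. The adjusted p ran from 0.00117 to 0.637 over 9 alternatives.

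Of 13 regulators of the mitochondrial stress response, 8 had a promoter peak (61.5%, log2 odds ratio 2.48 ± 0.79 SE, Fisher's exact test, adjusted p = 0.00344). The peak at cbp-1, the gene of the p300/CBP acetyltransferase, was the strongest at 4.62 ± 0.08 times the median (SD, n = 2), with rank 48, 859 bp upstream (chromosome III, 9765473 to 9765821), and another optimal summit was 105 bp from its 5' end. At atfs-1, which encodes the bZIP factor of the mitochondrial unfolded protein response, the summit was 38 bp upstream (chromosome V, 14193521 to 14193680) at 2.46 ± 0.55 (SD, n = 2). Peaks were also present at jmjd-1.2, a histone demethylase gene (2.3 ± 0.22), ubl-5, the gene of the ubiquitin-like partner of DVE-1 (1.85 ± 0.49), taf-4 (1.5 ± 0.22), zip-3 (1.43 ± 0.63), ulp-4, a SUMO protease gene (0.88 ± 0.54), and smo-1, the SUMO gene (0.80 ± 0.29), all as SD with n = 2. The jmjd-1.2 summit was also 330 bp upstream of F29B9.11 (460 bp for jmjd-1.2) and that of taf-4 635 bp upstream of pqn-59. The summit counted for zip-3 lay inside the gene, 692 bp upstream of an annotated 5' end within it. The windows of dve-1, hda-1, jmjd-3.1, lin-65 and met-2 held no optimal peak, and that of hda-1 held a region among the 7262 strongest of replicate 2 alone. Of the 13 genes, 7 had a region among the 7262 strongest of each replicate alone. This call was lost among genes with any region of the pooled list in the window (adjusted p from 0.00244 to 0.386 over 9 alternatives).

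**Figure D3:**
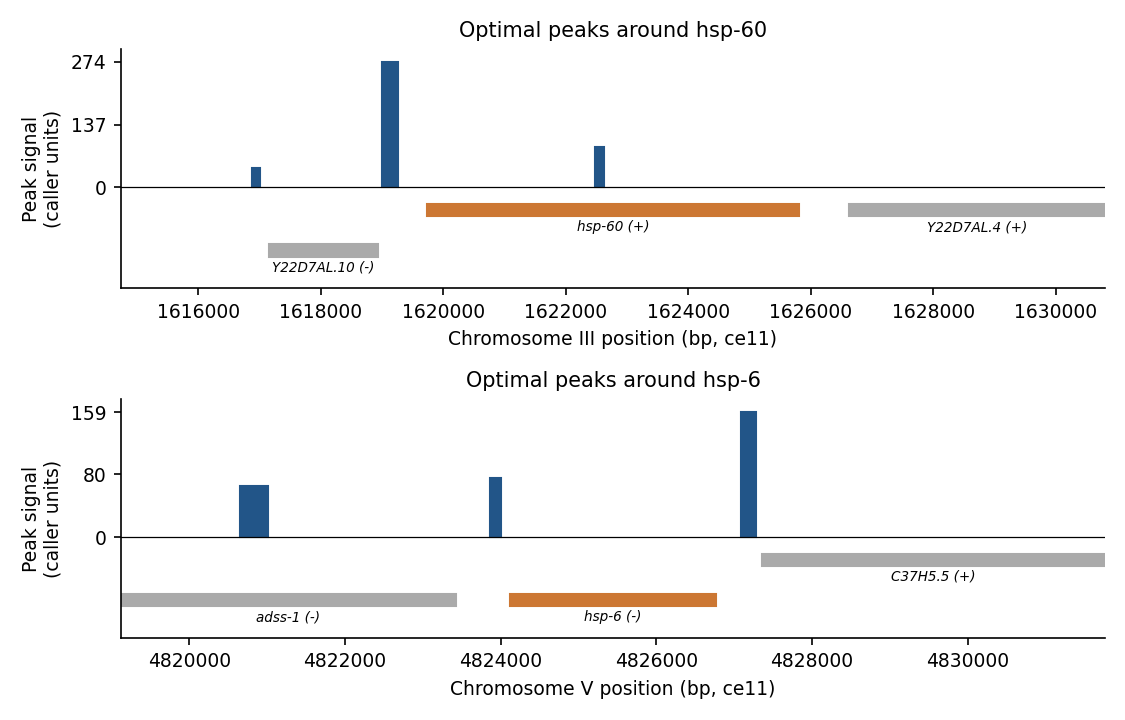
Optimal peaks (blue, height in the peak caller's units on the y axis) and protein-coding genes (grey, with the named gene in orange, the strand in brackets) around hsp-60 on chromosome III and hsp-6 on chromosome V, with ce11 positions in bp on the x axes. In both maps the highest peak, with a signal of 273.8 at hsp-60 and 159.4 at hsp-6, stands between the chaperone gene and a divergent neighbour.

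Across all 24 gene lists, genes for protein synthesis, folding and degradation and for energy metabolism had peaks more often than other genes. The highest share by promoter window was that of the cytosolic ribosomal protein genes, with 66 of 78 (84.6%; log2 odds ratio 4.29 ± 0.45 SE, Fisher's exact test, adjusted p = 2.97e-31). With each peak given only to the nearest 5' end within 2000 bp, in place of the promoter window, it was 39 of 78 (50%), still past the threshold. This was below endoplasmic reticulum stress (68.4%), intestine (64.5%) and vacuolar ATPase genes (55%) and the mitochondrial stress regulators (53.8%). That setting changed both the distance and the assignment, so the new order cannot be put down to either alone. Intestine genes with a peak rose from 16 to 20 of 31 under it. Genes of endoplasmic reticulum stress followed with 15 of 19 (78.9%, Fisher's exact adjusted p = 1.00e-06), among them xbp-1 (4.51 ± 0.09 times the median), the BiP gene hsp-3 (4.21 ± 0.06), atf-6 (2.80 ± 1.02) and the calreticulin gene crt-1 (2.58 ± 0.58; SD, n = 2). Peaks were found at 22 of 33 proteasome genes (rpn-3, pas-4, pbs-1, pas-5), 11 of 18 cytosolic heat shock genes (hsp-90, hsp-110, dnj-13, hsp-1) and 12 of 20 vacuolar ATPase genes (vha-12, vha-8, vha-1, vha-15). One peak served both rpn-3 and hsp-110. The pas-5 peak differed between replicates, with signals of 81 and 16. In energy metabolism, peaks were found at 22 of 38 genes of oxidative phosphorylation (cox-5A, cox-6B, cox-5B, atp-1) and 9 of 18 genes of glycolysis (pyk-1, aldo-2, hxk-3, pyk-2). Mitochondrial ribosomal proteins reached 30 of 70 (mrps-7, mrpl-23, mrpl-28, mrps-31) and aminoacyl-tRNA synthetases 12 of 31 (ears-2, aars-1, fars-1, mars-1). The summit counted for mrpl-23 lay inside fars-1, its upstream neighbour on the same strand, and cannot be assigned to mrpl-23 with certainty. Whether closely spaced genes of the same strand have promoters of their own was not tested. Adjusted p for these 7 lists lay between 2.86e-07 and 0.0377.

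Lists of tissue and environmental response genes were marked unevenly. Intestine genes had peaks at 16 of 31 (51.6%, Fisher's exact adjusted p = 0.000433), among them the GATA factor gene elt-2, the protease gene asp-1, the actin gene act-5 and pgp-1. Detoxification enzymes had them at 67 of 188 (35.6%, exact adjusted p = 2.82e-05; ugt-20, gst-42, gst-27, ugt-50) and nuclear hormone receptors at 93 of 269 (34.6%, exact adjusted p = 4.47e-06; nhr-68, nhr-47, nhr-119, nhr-58). By the same Fisher's exact test, 4 families were marked less often than other genes. Chemoreceptor-type receptors had peaks at 23 of 1293 (1.78%, log2 odds ratio -4.02 ± 0.30 SE, exact adjusted p = 1.62e-104; strongest at srh-282, srh-2, srh-70 and sri-5), and the srh-70 peak was also that of ceh-99. Cuticle collagens had them at 11 of 156 (7.05%, exact adjusted p = 4.47e-06; col-38, col-63, col-71, col-74). The neuropeptide and insulin-like families had them at 10 of 140 (7.14%, exact adjusted p = 1.32e-05; ins-39, ins-7, ins-12, nlp-4), and C-type lectins at 27 of 240 (11.2%, exact adjusted p = 8.69e-05; clec-126, clec-150, clec-265, clec-170). The lists of homeobox factors (11 of 87; ceh-38 and ceh-99), innate immunity (12 of 32; zip-2 and spp-1), muscle (6 of 32; unc-112 and pat-6), germ line (3 of 33; nos-3 and gld-2), neurons (3 of 32; snb-1 and unc-25) and histones (14 of 72; his-37 and his-3) did not pass, with adjusted p from 0.0593 to 0.832. Homeobox factors, with fewer marked genes, passed in 7 of 9 alternatives, those without replicate 1 and without replicate 2 among them, and innate immunity, with more, in 5 of 9. Neurons and germ line, with fewer, passed in 3 of 9 each. Among these were neurons without replicate 2 (0 of 32, exact adjusted p = 0.00118) and germ line without replicate 1 (2 of 33, exact adjusted p = 0.0403). In all, 18 of 24 lists passed, 14 with more and 4 with fewer marked genes.

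When the background was limited to the 7732 genes with any region of the pooled list in the window, of which 56.0% had an optimal peak, 5 lists passed and 4 of the 18 kept their call, namely cytosolic ribosomal proteins, endoplasmic reticulum stress, nuclear hormone receptors and collagens; the list of neurons was added, with fewer marked genes. The aminoacyl-tRNA synthetases kept their call in 3 of 9 alternatives (adjusted p from 0.0207 to 1) and lost it, among others, without replicate 2. The mitochondrial ribosomal proteins also lost theirs with each peak given to the nearest 5' end within 2000 bp (21 of 70).

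**Figure D4:**
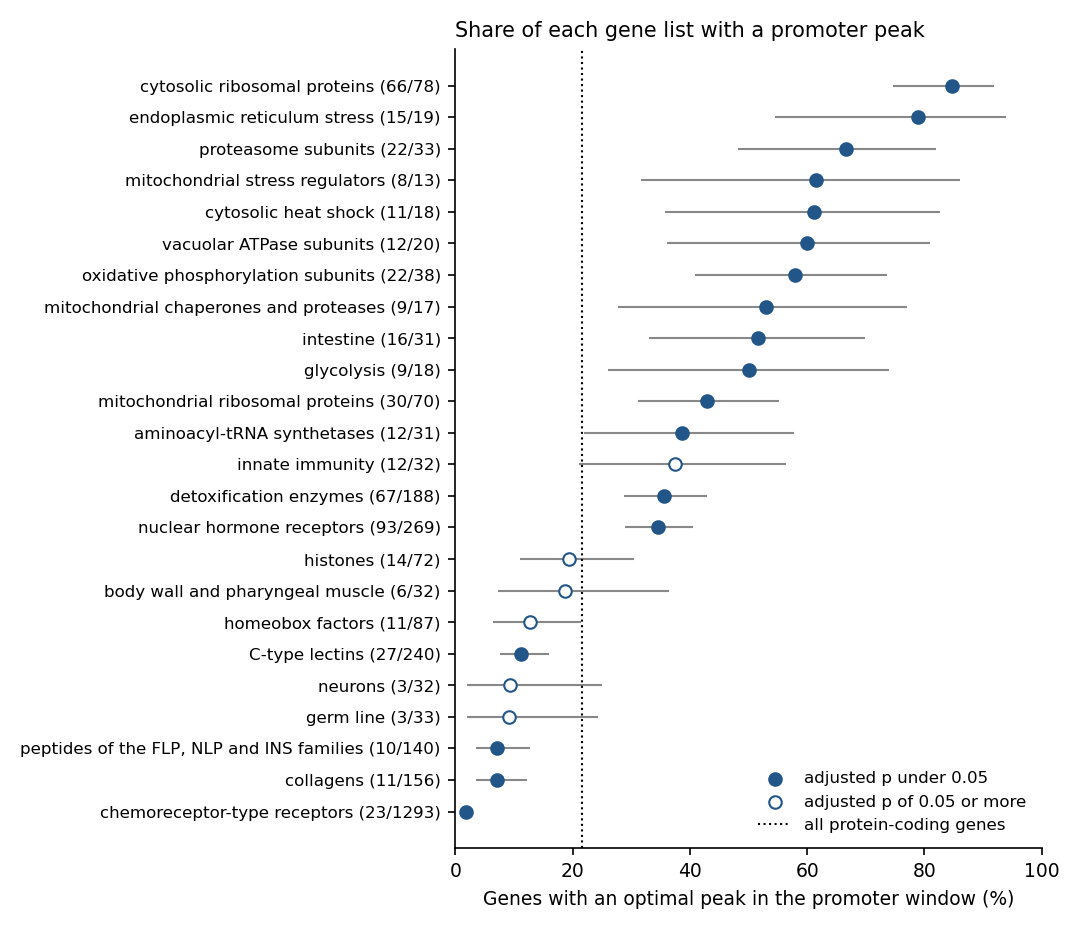
Share of the protein-coding genes of each list with an optimal peak in the promoter window (points, x axis in percent) with 95% exact intervals, the number of marked and of all members beside each name, and a dotted line at the share among all protein-coding genes, 21.7%. Filled points mark the 18 lists with an adjusted p under 0.05, from cytosolic ribosomal proteins at 84.6% to chemoreceptor-type receptors at 1.78%.

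Peaks were also found near genes for small RNAs. In 418 peaks (5.76%, 95% exact interval 5.23 to 6.32) the summit lay within 300 bp of a tRNA, snRNA, snoRNA or rRNA gene, against a mean of 0.744% and at most 1.62% for shifted peaks (one-sided p = 0.0001, the smallest that 10000 shifts can give). Transfer RNA genes accounted for 270 of these peaks, and 306 of the 612 annotated tRNA genes (50%) had a summit within that distance. The same held for 105 of 346 snoRNA genes (30.3%) and 37 of 129 snRNA genes (28.7%), of which 30, 15 of them with a summit, are spliced leader genes. None of the 20 annotated rRNA genes had one. Shifted peaks lay near rRNA genes in a mean of only 0.018% of cases, so this absence carries no weight. Many tRNA genes have identical copies, between which reads cannot be told apart, and unspecific signal at strongly transcribed genes is known in such experiments.

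Chromosome X carried more peaks than its length would give. It held 1591 of the 7262 peaks (21.9%, 95% exact interval 21 to 22.9), while it makes up 17.7% of the nuclear genome (ratio 1.24, two-sided exact binomial test, p = 3.68e-20, with peaks taken as independent). Peak density was 89.8 per Mb on X and between 61.5 (chromosome V) and 82.1 (chromosome III) on the autosomes. Promoter windows held 45.8% of the peaks on X, against 56.5% to 59.3% on each autosome. The share of each chromosome within promoter windows was not measured, so this difference does not show another placement on X. X also has 13.7% of the protein-coding genes, and against that share the ratio was 1.6. Median signal on X, 64.7, lay within the range of the autosomes (62.2 to 66.1).

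Because the strain carries the tagged dve-1 as a transgene and its genotype names unc-119, both loci were examined for extra peaks. A count of peaks does not measure signal, so raised signal from extra copies was not tested. Within 20 kb of dve-1 (chromosome X, 427035 to 433812, minus strand) there was 1 optimal peak, and within 20 kb of unc-119 (chromosome III, 10902641 to 10908935, plus strand) there were 0, where the median protein-coding gene had 3. The count at dve-1 stood at the 19.8th percentile of genes. The promoter windows of both genes were without a peak. On the ce10 assembly the optimal list held 7276 peaks, 14 more than on ce11, with 1592 on X.

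The sequence at summits differed from that nearby. Of 2080 6-mers (each with its reverse complement), 1388 differed in frequency between the 50 bp on each side of the summit and flanks of the same total width centred 300 bp away, 809 more frequent at summits and 579 less frequent (exact McNemar test over 7262 peaks, Benjamini-Hochberg adjusted p under 0.05). The most significant was GATAAG, the core of the site of GATA factors, present at 1496 summits (20.6%) and 266 flanks (3.66%; log2 ratio 2.49, exact adjusted p = 5.14e-219). TGATAA (29.3% against 10.1%) and CTGATA (14.9% against 4.41%) overlap it. Others were rich in GA, with GAGAGA (21.2% against 6.25%), AGAGAG (18.3% against 5.08%) and AAGAGA (20.5% against 8.08%). AGAGAC (15.7% against 3.73%), CGTCTC (13.2% against 2.89%; GAGACG on the other strand), GACGCA (11.4% against 2.0%) and ACGCAG (11.6% against 2.0%) overlap in sequence, and 460 of the 845 summits with ACGCAG (54.4%) held the longer GAGACGCAG. The most significant of the 6-mers less frequent at summits were AT-rich, with AAAATT at 20.6% of summits and 44.9% of flanks, followed in adjusted p by TTAAAA, AAAAAT, TTTAAA and AAATTT. GC content was 41.4% at summits and 34.8% in flanks. The test was not corrected for this difference, and only GATAAG was compared with other 6-mers of the same bases. At the 7262 weakest regions of the pooled list, 54 6-mers passed, GC content was 33.8% at summits and 35% in flanks, and GATAAG was at 3.95% and 3.54%.

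**Figure D5:**
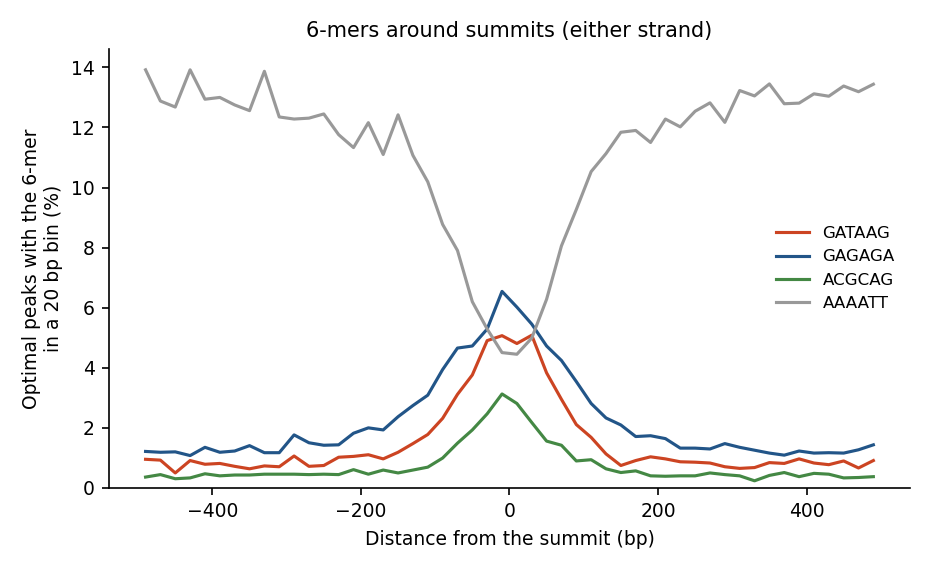
Share of optimal peaks (y axis, percent) with GATAAG, GAGAGA, ACGCAG or AAAATT on either strand in each 20 bp bin, by distance from the summit (x axis, bp). The first 3 rise towards the summit, GAGAGA up to 6.54% of peaks per bin, and AAAATT falls to 4.45%.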

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

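The tests on identical tRNA copies, on the 6-mers at tRNA peaks and on intestine genes were set down before their results were seen. Those on snRNA genes, tissues, upstream distance, called regions and base composition were chosen only after the data were seen.

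The pooled list held 2098 regions with the highest q value that are not in the optimal list, a signal in data outside the main measurement. They entered the report only through the background of genes with any pooled region and the windows of single genes. Their signal ran from 25.8 to 34.7, just under the optimal peaks. Of these regions, 905 (43.1%) had a summit in a promoter window, against a mean of 25.7% and at most 28.8% over 1000 circular shifts (one-sided permutation p = 0.001, the smallest they can give), and 14.5% held GATAAG within 50 bp of the summit. Both replicates had a region with their own highest q value within 100 bp for 490 of them (23.4%), against 87.4% of the optimal peaks, a difference that the cut on signal between them can give by itself.

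Peaks lay at 50% of tRNA genes. Reads shared between copies stay open as a cause. Of the 143 tRNA genes with a sequence of their own, 33.6% had a peak (95% exact interval 25.9 to 41.9), above the highest value of 11.2% over 100 shifts. But a gene counted as having its own sequence if any base differed. A summit within 300 bp can also belong to a neighbouring copy, so the test cannot exclude shared reads. The share among copies with an identical partner was 55%. The 6-mers of other summits were less frequent at tRNA peaks. Of these peaks, 25.9% held GATAAG, GAGAGA or ACGCAG, against 45.9% of other peaks (Fisher's exact test, p = 5.3e-11). The prediction for these 6-mers as a cause, a share at least as high as in other peaks, was not met. Most other peaks also lacked them, so the test cannot decide whether they are the whole cause. The 6-mers were picked from the scan of the same optimal peaks. The flanks of tRNA peaks were not measured, so a part of the 6-mers in some of these peaks stays open. Unspecific signal at strongly transcribed genes stays open: snRNA genes had peaks at 28.7%, less often than tRNA genes and above the 9.3% of the highest shift. The class includes 30 spliced leader genes, without which 22 of 99 (22.2%) had one. An immunoprecipitation without the tagged protein was not analysed here.

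Gene lists differed widely, from 1.78% to 84.6% of genes with a promoter peak. Unspecific signal at active genes of every tissue stays open. Muscle and germ line genes had a peak at 9 of 65 (13.8%) beside 16 of 31 intestine genes (51.6%), but among genes with any pooled region in the window at 9 of 15 (60%) beside 16 of 27 (59.3%). Cytosolic ribosomal protein genes, which are active in every tissue, had the highest share by promoter window. With each peak given only to the nearest 5' end within 2000 bp, in place of that window, their share was 39 of 78, below that of other lists. The share of chromatin from each tissue was not measured. Room upstream of the gene was argued against, as 17 of 18 lists kept their call with the distance to the upstream gene as a covariate. That lists differ only in whether a gene has any called region was argued against as the whole cause. Among genes with any pooled region, 4 lists kept their call and 16 of 18 their direction, with a median log2 odds ratio in the main direction of 0.77 (bootstrap interval over lists 0.47 to 1.42), against 1.98 among all genes. The 18 lists and their directions were selected by the main test on the same peaks, which favours this count and median. The argument therefore rests on the 4 lists alone. The calls of 14 lists were lost, with smaller ratios and fewer genes, and for these that cause stays open. That background comes from the same immunoprecipitation, so it would also take away part of a true difference.

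GATAAG was the most significant 6-mer at summits. Base composition was argued against as its cause, since its log2 ratio of 2.49 lay above those of all 58 other 6-mers of the same bases without GATAA (-1.08 to 1.35, median -0.10). A candidate explanation is that these are sites of intestinal GATA factors such as ELT-2, to which DVE-1 would be recruited or beside which it would bind. It cannot be told apart from chance here: 37.5% of 16 intestine promoter peaks held GATAAG against 19.1% of other promoter peaks (Fisher's exact test, p = 0.101).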

How the results depend on the processing

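The alternative that took the strongest pooled regions was void, because these are the optimal peaks themselves. So was the rank correlation in the 3631 weakest peaks (-0.16), which were selected on the pooled signal of the same replicates. Both of these alternatives are left out of the counts here. The 3631 strongest peaks (0.66) and the whole optimal list (0.71) were selected on that signal too, so their correlations are also affected by it. Of 60 other alternatives to the main values, 54 kept their direction, their side of the threshold and, for counts, stayed within 1.5 times the main count. Replicate overlap ran from 57.0% to 79.0%, the promoter share from 42.8% to 68.5% with the window, the X share from 21.2% to 22.0%, and the 6-mers past the threshold from 1239 to 1464. Without replicate 1 or without replicate 2, the promoter share was 54.5% and 53.7%, and both gave 20 lists past the threshold. Leaving out peaks near small RNA genes, an alternative chosen after the data were seen, gave 21 lists, all 18 of the main lists among them. In the 3631 strongest peaks the log2 difference of promoter peaks was 0.0192. Among genes with any pooled region in the window 5 lists passed. Aminoacyl-tRNA synthetases turned to a log2 odds ratio of -0.21 in the strongest peaks and -0.35 with that background, and C-type lectins to 0.80 with that background. The percentile at dve-1 was 0 in the strongest peaks and within 10 kb, and from 0 to 18.5 without a replicate; that of unc-119 was 15.4 within 40 kb. For these changes the cause was not tested. Among 216 alternatives for single lists, 177 left the call as it was, 18 lost it, 18 gained one (homeobox factors in 7, innate immunity in 5, neurons and germ line in 3 each) and 3 turned its direction. Of the 18 main lists, 4 passed in every alternative and 11 were lost in 1. Single peaks were not tested here beyond the deposited calls, and unknown depth leaves open whether genes without a peak were out of reach.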

Other observations

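The tests here were all chosen after the data were seen. The 6-mers at summits were not spread evenly over gene groups. None of the 63 promoter peaks of cytosolic ribosomal protein genes held GATAAG within 50 bp of the summit, against 19.6% of other promoter peaks (Fisher's exact test, adjusted p = 0.00016 over 72 tests of 24 lists and 3 6-mers). Promoter peaks of C-type lectin genes, which were few, held it at 15 of 25 (60% against 18.9%, exact adjusted p = 0.000266). Those of nuclear hormone receptor genes held ACGCAG at 26 of 93 (28% against 13.5%, exact adjusted p = 0.00804). None of the 15 strongest promoter peaks held GATAAG or GAGAGA, and 3 held ACGCAG (iff-2, rps-19 and rpl-12). At atfs-1 the summit held all 3 6-mers and at cbp-1 it held GAGAGA, while hsp-6 and hsp-60 held none of them. GATAAG and GAGAGA met at 221 summits, fewer than the 317.7 of independent placement (Fisher's exact test, p = 1.83e-12). Peaks with ACGCAG and GAGAGA were stronger than those without (log2 differences of 0.24 and 0.18, permutation test, adjusted p = 0.00015 for both), and for GATAAG the difference was 0.01 (adjusted p = 0.741). This median hides an uneven course. In 5 groups of peaks of falling strength GATAAG was at 17.9%, 22.6%, 23%, 21.1% and 18.4%, and it was at 4 of the 100 strongest peaks. On X, GAGAGA was at 17% of summits and ACGCAG at 7.48%, against 22.4% and 12.8% on autosomes (Fisher's exact test, adjusted p = 8.25e-06 and 7.04e-09 over 6 tests), and GATAAG was at 21.1% and 20.4% (exact adjusted p = 0.575).

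Peak strength also differed between groups. Promoter peaks of oxidative phosphorylation genes had a median signal of 143.3 and those of cytosolic ribosomal protein genes 129.2, against 69.9 and 69.6 for other promoter peaks (permutation tests over 24 lists, adjusted p = 0.0012 for both). Genes of endoplasmic reticulum stress (147, permutation adjusted p = 0.0024), cytosolic heat shock (148.3, adjusted p = 0.0048) and histones (150.3 over 10 peaks, adjusted p = 0.003) also had stronger peaks. The proteasome genes, of which 22 of 33 were marked, had a median of 71.2 (permutation adjusted p = 0.909). Neither mitochondrial stress list passed. The chaperones and proteases had a median of 102.3 over 9 peaks (permutation adjusted p = 0.261). The stress regulators had 113.7 over 8 peaks (permutation adjusted p = 0.0987). Spliced leader RNA genes parted by kind. Of 18 SL2 genes, 15 had a summit within 300 bp, with a median signal of 151.9 over 19 peaks, 3 of them among the 100 strongest. None of the 12 SL1 genes had one, and these lie in a tandem repeat with 5S rRNA genes, where reads are hard to place.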
